A study of Homo sapiens with 10 samples.

How the data were processed

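RNA of 10 MCF-7 subclones was measured on single-colour Agilent arrays, 1 array per subclone. Per the labels' protocols, cells were grown in RPMI medium with foetal calf serum, total RNA was extracted with Trizol, and the RNA was amplified to antisense RNA and labelled with Cy3. Scanner images were turned into spot intensities by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers; the processed intensity is background-subtracted and detrended within each array, is on a linear scale and is not scaled between arrays. Per the file headers the array design was annotated to the hg19 build. The title given to subclone 1 carries the letter V and the titles of the other 9 carry the letter T, which the labels do not explain. TIMP1 protein levels in ng per mg protein and the classes low (2 subclones), intermediate (2) and high (6) were taken from the labels, which do not say how the protein was measured or that the subclones came from separate cultures. The response to fulvestrant was not analysed here.

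Each array held 43118 spots of 34127 probes besides 1377 control spots. Log2 of the processed intensity was centred on the array's 75th percentile over non-control spots, spots that the scanner software marked as outliers were left out, spots of 1 probe were averaged, and 23977 probes well above background on at least 2 of the 10 arrays were kept, 300 of them without a usable spot on at least 1 array. No spot was saturated. Between 55.2% and 68.2% of probes were well above background per array, and the 75th percentile ran from 997 to 1457. The number of arrays limits the precision. No 2 arrays were near duplicates, the smallest root mean square difference between arrays being 0.418 on the log2 scale. Probes were named through the accession in the files and a RefSeq table of assembly GRCh38.p14, which was used only for symbols and for the order of neighbouring genes. That gave 1 symbol to 25419 probes, several to 0 and none to 8708, which may have genes and are left unnamed; 19126 kept probes named 14835 genes. Where a gene had several probes, those with a usable spot on all 10 arrays came first, and of these the one with the highest mean was used. Disagreement of the others is stated.

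Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all kept probes, threshold 0.05), with 1 fit on log2 TIMP1 protein over 10 subclones, 1 fit of the 3 classes with a shared spread for the contrasts between them, and 1 fit of high against low and intermediate together. An adjusted p given without another test's name is limma's for a gene and camera's for a gene list. Gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation; of 415 list entries 408 were on the array by name and 357 were tested. Correlations with TIMP1 protein used 100000 permutations, or all permutations for 8 or 9 subclones, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The comparisons, the alternatives below except where stated, the lists and the rule for naming genes were set before the data were examined. The rule named TIMP1, PGR and ESR1 always; for the trend and for high against low the 12 largest coefficients in each direction among genes past the threshold, for the latter only where the 6 high subclones lay on one side of both low ones; for other comparisons the 5 largest in each direction; in each list up to 4 members past the threshold; and, where fewer than 10 genes passed, the 10 with the smallest p. Raising dim signals to the detection floor for genes measured on part of a class's arrays and for trend slopes, and fitting each ESR1 probe, were chosen after values were seen.

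The 26 lists were oestrogen receptor target genes, luminal epithelial identity, basal epithelial markers, mesenchymal and EMT genes, metalloproteinases and their inhibitors, TIMP1 surface partners and integrins, ERBB receptors and ligands, MAP kinase feedback genes, IGF and insulin signalling, anti-apoptotic genes, pro-apoptotic genes, cell cycle and proliferation, cell cycle inhibitors and p53 targets, interferon-stimulated genes, NF-kB targets and cytokines, hypoxia and glycolysis, cholesterol synthesis, unfolded protein and amino acid stress response, heat shock genes, drug transporters and detoxification, topoisomerases, genes near TIMP1 on the X chromosome, steroid receptors and their cofactors, fibroblast markers, blood and endothelial cell markers, and housekeeping genes. A gene in more than 1 list was counted in each.

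On simulated data with 200 changed probes among the 23677 without missing values, changes of 0.5, 1, 2 and 4 on the log2 scale were recovered at 0%, 53.5%, 85.0% and 98.0% in high against low, 0%, 17.5%, 77.5% and 95.0% in intermediate against low, 0%, 46.0%, 83.5% and 96.5% in high against intermediate, 0%, 60.0%, 90.5% and 100% in high against the rest, and 0%, 13.0%, 75.0% and 95.0% in the trend, where a change is that over the whole range of protein.

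Alternatives were quantile normalisation; normexp background correction with offset 50 followed by quantile normalisation; scaling to the median; no filter on dim probes, or probes well above background on all 10 arrays; eBayes with trend and robust; array weights; the authors' table of processed values; the slide as a fixed or random block; TIMP1 protein unlogged or as ranks, or TIMP1 mRNA in its place; the mean of a gene's probes; only the groups compared; and each subclone left out in turn. Added after the data were seen were the negative-control signal of each array as a covariate, leaving out subclones 2 and 6, and the arrays of a single slide. Normexp was planned on the mean spot signal, which the files used here do not hold, and was run on the median spot signal with the median local background. The authors' deposited table held linear intensities for 34183 probes with a column median of 134 to 138 and the same maximum, 495156, in every column; its columns ranked spots like the median signal (Spearman 0.9997 or higher), so its scale and direction are known, while its normalisation is not given in the sources used here.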

Results

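Gene expression was measured in 10 subclones of MCF-7, an established human breast cancer cell line that expresses the oestrogen receptor, with 1 single-colour array per subclone. The labels sort the subclones by their content of TIMP1, a secreted inhibitor of the metalloproteinases that degrade extracellular matrix. The low class held 2 subclones (1.88 and 11.09 ng TIMP1 per mg protein), the intermediate class 2 (35.24 and 65.63) and the high class 6 (84.38 to 434.59). Subclones keep their label numbers: 1 and 2 are low, 3 and 4 intermediate, and 5 to 10 high. Subclone 1 alone has the letter V rather than T in its title. If the letter marks another kind of subclone, that cannot be told apart from its TIMP1 level, the lowest of the 10. The labels do not say that the subclones came from separate selections or cultures, so each p-value measures only the spread between these 10 subclones, which may in part be technical, and the number of arrays limits the precision. The title of the series names TIMP1, resistance to fulvestrant (a drug that degrades the oestrogen receptor) and the progesterone receptor as its subject, and the comparisons follow the TIMP1 level. Signals are given as log2 relative to the array's 75th percentile, and 23977 probes naming 14835 genes were tested.

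The 6 high subclones formed a group of their own. Component 1 of a principal component analysis held 41.3% of the variance and separated the high subclones (16.1 to 52.1) from the low and intermediate ones (-71.8 to -33.1). Pairs of high subclones correlated at 0.982 to 0.992 across probes, pairs of a high with a low or intermediate subclone at 0.964 to 0.976, and pairs among the low and intermediate subclones at 0.964 to 0.991. These correlations are across probes, which are not independent replicates. Component 2 (17.5% of the variance) ran from subclone 2 (-74.5) to intermediate subclone 3 (53.6), and subclone 6 stood apart on component 3 (-61.3, 9.0%). The arrays of subclones 2 and 6 had the most spots left out as outliers, 645 and 531, against 201 to 283 on the other 8. The signal of the negative control spots was 43.4 to 100.2 on the low and intermediate arrays, highest for subclone 3. It was 63.9 on the array of high subclone 6 and 30.8 to 34.9 on the arrays of the other 5 high subclones. The arrays lay on 3 slides: slide 1 held the 2 low subclones and high subclones 5 and 6, slide 2 held intermediate subclone 4 and high subclones 7, 9 and 10, and slide 3 held intermediate subclone 3 and high subclone 8.

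**Figure D1:**
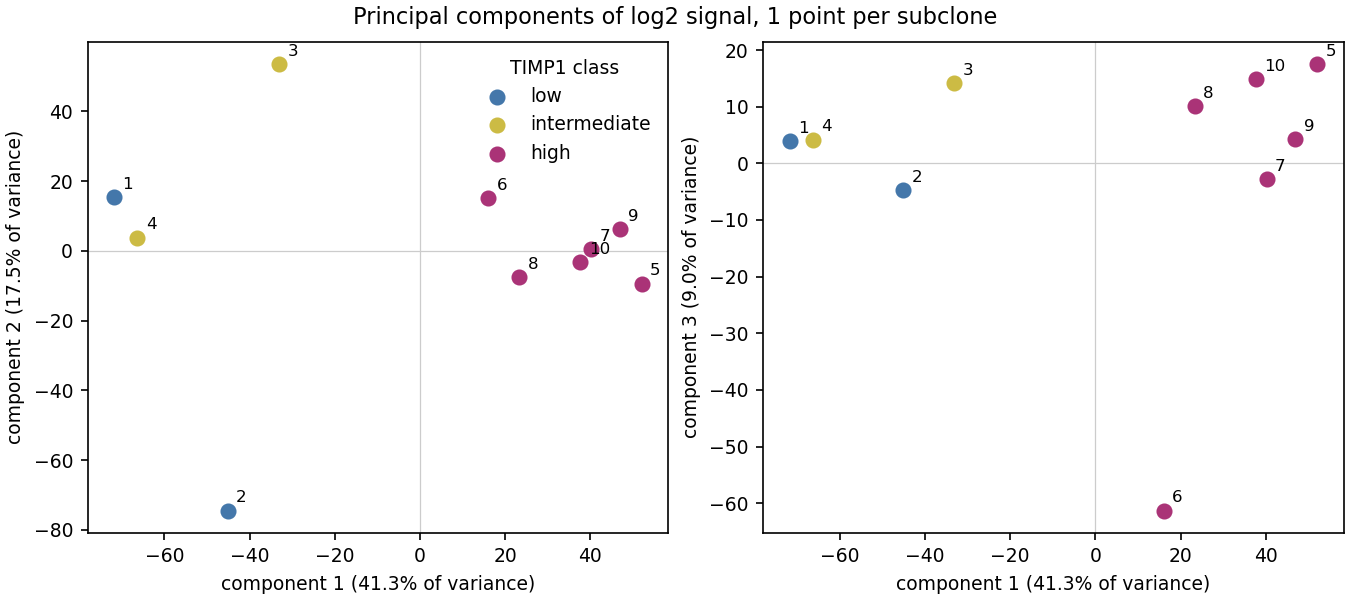
Scores of the 10 subclones on principal components 1 and 2 (left) and 1 and 3 (right) of the log2 signals, 1 point per subclone, coloured by TIMP1 class and numbered as in the labels. The 6 high subclones lie between 16.1 and 52.1 on component 1, and the low and intermediate ones between -71.8 and -33.1.

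TIMP1 mRNA followed the protein level given in the labels. Its log2 signal was 1.55 and 2.88 in the low subclones, 4.24 and 4.62 in the intermediate ones and 6.07 ± 0.28 (SD, n = 6) in the high ones. Over the 10 subclones, log2 TIMP1 signal and log2 protein correlated at r = 0.965 (permutation p = 4e-05, adjusted p = 0.00012) and rho = 0.915 (permutation p = 0.00052, adjusted p = 0.00156), both two-sided and adjusted over the planned family of 3 genes. Of these 3, PGR was not tested for correlation, and its p was assumed to be the largest. Without subclones 1 and 2, which lie farthest from the median protein level, r was 0.826 (n = 8, exact permutation p = 0.00697, adjusted p = 0.0209) and rho 0.833 (exact permutation p = 0.0154, adjusted p = 0.0461). The slope of TIMP1 signal per doubling of protein was 0.69 over all arrays, 0.69 within the 4 arrays of slide 1 and 0.44 within the 4 of slide 2, and on slide 3 the high subclone exceeded the intermediate one by 1.82. Within the 6 high subclones alone the slope was 0.17. With unlogged protein r was 0.67 (permutation p = 0.0384, adjusted p = 0.115) and rho was the same by construction.

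PGR, the progesterone receptor and a classical target gene of the oestrogen receptor, was expressed in the low and intermediate subclones. On the probe used here, the one with a usable spot on all 10 arrays, it was not well above background in any of the 6 high ones. Its log2 signal was -1.37 and -1.47 in the low subclones and -2.31 and -2.36 in the intermediate ones. PGR was at least 28.2-fold lower in high than in low subclones (limma, adjusted p = 0.000875) and at least 14.96-fold lower in high than in intermediate ones (limma, adjusted p = 0.00168), lower in 6 of 6. Both calls held after blocking on slide (limma, adjusted p = 0.0239 and 0.0222), and with the negative-control signal of the arrays as a covariate the call against low held (adjusted p = 0.00835) and that against intermediate did not (adjusted p = 0.13). On this probe PGR was at least 17.7-fold lower in the high than in the low subclones on slide 1, and at least 19.0-fold and 17.9-fold lower than in the intermediate one on slides 2 and 3. A bound of this kind sets the mean of the brighter class against the detection floor of the dimmer class, which is, per array, the higher of the gene's own signal and the lowest signal of any probe well above background. Where only part of a class was below background, "at least" gives the difference with those arrays raised to the floor, and the p stays that of the fitted values. A second PGR probe gave the same direction in high against low, but had no usable spot in subclone 2. It was well above background in high subclone 8, at -4.86, against -2.47 in intermediate subclone 3. On that probe the difference on slide 3 was therefore smaller than the bound, and the bounds given for PGR are those of the probe used. PGR values fell into 2 clusters, and those of the high subclones have no order below the floor, so no correlation of PGR with TIMP1 protein is given. ESR1, the gene of the oestrogen receptor that fulvestrant targets, had a log2 signal of 0.36 ± 0.10 (SD, n = 2) in low, 0.28 ± 0.15 (n = 2) in intermediate and 0.19 ± 0.26 (n = 6) in high subclones. Its difference between high and low was -0.17 (SE 0.19; limma, adjusted p = 0.586) on the brightest probe, and -0.49 (SE 0.21, adjusted p = 0.166) and -0.47 (SE 0.20, adjusted p = 0.163) on the other two, none past the threshold. ESR1 signal did not correlate detectably with log2 TIMP1 protein (n = 10, r = -0.205, permutation p = 0.544, adjusted p = 0.816; rho = -0.018, permutation p = 0.974, adjusted p = 1). For the mean of the 3 probes r was -0.544 (permutation p = 0.113, adjusted p = 0.17) and rho -0.479 (permutation p = 0.166, adjusted p = 0.25). Without subclones 1 and 2, r for ESR1 was 0.219 (n = 8, exact permutation p = 0.595, adjusted p = 0.892).

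**Figure D2:**
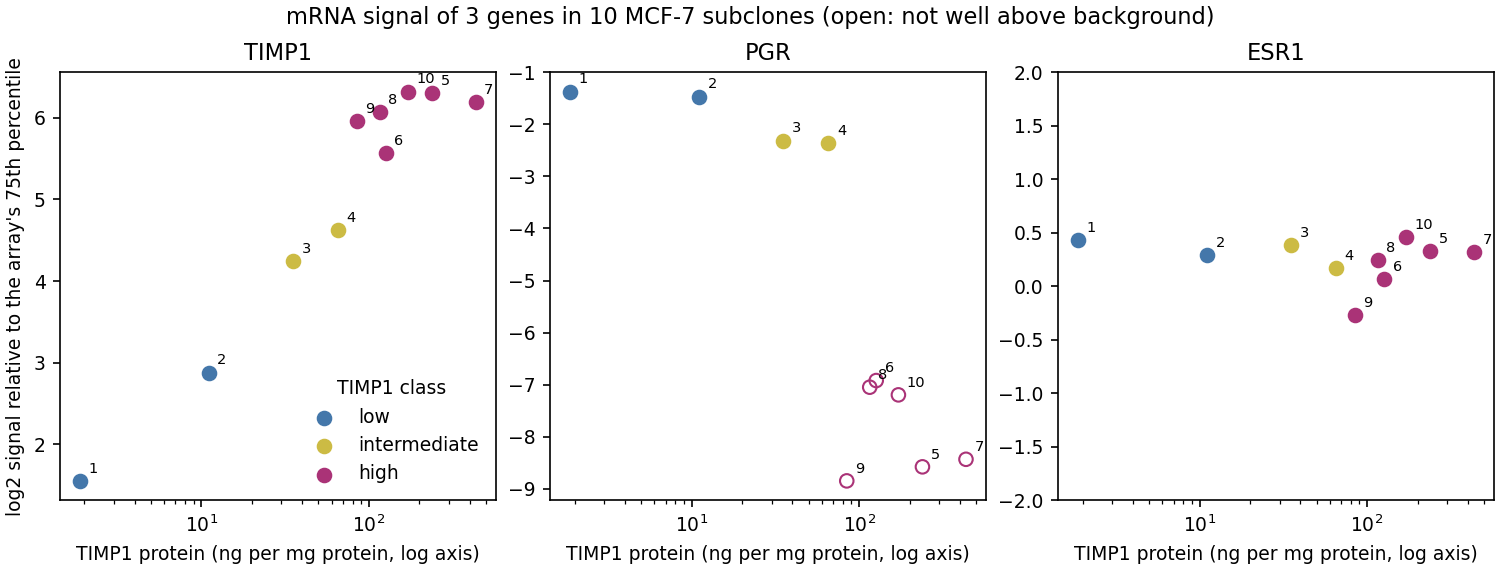
Log2 signal of TIMP1, PGR and ESR1 in each of the 10 subclones (vertical axes, relative to the array's 75th percentile; 1 point per subclone, coloured by class) against TIMP1 protein in ng per mg protein on a log axis, with open points not well above background. TIMP1 signal runs from 1.55 to 6.32, PGR is at -2.36 or higher in the low and intermediate subclones and open in the 6 high ones, and ESR1 lies between -0.27 and 0.46.

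The first comparison asked which genes changed in step with TIMP1 protein across all 10 subclones. Of the genes that passed, TIMP1 itself had the largest slope, 0.69 on the log2 scale per doubling of protein (SE 0.06; limma, adjusted p = 0.00726). HOTAIR, a long non-coding RNA from the HOXC cluster, rose by 0.48 per doubling (SE 0.05, adjusted p = 0.0132), CSGALNACT1, an enzyme of chondroitin sulphate synthesis, by 0.42 (SE 0.06, adjusted p = 0.0476), and AHDC1 by 0.23 (SE 0.03, adjusted p = 0.0476). ROBO2, a receptor for the guidance protein SLIT, fell by 0.37 per doubling (SE 0.05, adjusted p = 0.0476) and GPR158, an orphan receptor of the brain, fell by 0.63 (SE 0.08, adjusted p = 0.0425). HOTAIR and CSGALNACT1 were not well above background in any low or intermediate subclone and were measured in 5 of the 6 high ones. GPR158 was measured in the 4 low and intermediate subclones and in no high one, and ROBO2 in both low, 1 intermediate and 1 high subclone. With signals below background raised to the floor, the slopes were 0.15 for HOTAIR, 0.17 for CSGALNACT1, -0.28 for ROBO2 and -0.45 for GPR158. COL24A1, a fibrillar collagen measured in 3 high subclones alone, passed as well (adjusted p = 0.0407), but its slope was -0.01 with the floor, so its direction cannot be read. The second AHDC1 probe did not share the trend (slope -0.00). In all, 10 of 23977 probes passed the threshold of 0.05 by limma, 7 with a positive and 3 with a negative slope, and 5 and 2 of them name these genes.

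Next in the ranking and not past the threshold, each with an adjusted p of 0.054, came ADCY5, an adenylyl cyclase (slope 0.45, SE 0.06), RIMS1, a scaffold of synaptic vesicle release measured in 5 high subclones alone (0.32, and -0.00 with the floor), and IRX2, an Iroquois homeobox factor (-0.25, SE 0.04). The slope of PGR was -1.13 (SE 0.24; limma, adjusted p = 0.0916; -0.83 with the floor) and that of ESR1 -0.02 (SE 0.03, adjusted p = 0.745). The small count of trending probes depended on single subclones: it was 0 without subclone 1, 5 without subclone 2, 1441 without subclone 4, 4 without subclone 5, 6, 7 or 9, 6 without subclone 8 and 5 without subclone 10, and none of the 7 genes was called in each of these 10 fits. The count was also 0 with the slide as a fixed block and within slide 1 or slide 2 alone, and 71 with the slide as a random block. With the fixed block the slopes of the 7 genes kept 0.983 to 1.09 of their size, so their calls ended by wider errors.

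Among the 26 planned gene lists, 3 shifted upwards with TIMP1 protein by camera with its preset correlation. None of the 3 calls held with a correlation estimated from the data (adjusted p = 0.606 with an estimated correlation for each). The MAP kinase feedback genes, which the ERK pathway induces and many of which restrain it, had a median slope of 0.13 (15 genes, adjusted p = 0.00063). Of these genes 0 passed over all probes, while 8 were higher and 0 lower when adjusted over the list alone, among them PHLDA1 (0.60, well above background in 1 of the 4 low and intermediate subclones), ETV5 (0.42, in 2 of the 4), FOS (0.29) and DUSP4 (0.22), a phosphatase that inactivates MAP kinases. The cell cycle inhibitors and p53 targets had a median slope of 0.11 (14 genes, adjusted p = 0.00166). Adjusted over the list alone, 7 were higher, such as BTG2 (0.31), GADD45A (0.25), GDF15 (0.19) and CDKN1A (0.16), the gene of the cyclin-dependent kinase inhibitor p21, and 1, RRM2B (-0.08), was lower. The cholesterol synthesis genes had a median slope of 0.06 (15 genes, adjusted p = 0.00396), with HMGCS1 (0.19), MSMO1 (0.14) and IDI1 (0.09), enzymes of the mevalonate and sterol pathway, higher when adjusted over the list alone. The other 23 lists had an adjusted p of at least 0.119. Among these, median slope, mean slope and camera's direction differed in sign for IGF and insulin signalling, interferon-stimulated genes, heat shock genes, drug transporters, topoisomerases, steroid receptors, and blood and endothelial markers.

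All 3 list calls were also lost without subclone 1, with adjusted p = 0.0621 for MAP kinase feedback, 0.362 for the inhibitors and 0.132 for cholesterol synthesis. With unlogged TIMP1 protein the cholesterol synthesis genes no longer passed (adjusted p = 0.0815). All 3 still passed with the slide as a block (adjusted p = 0.000303, 0.00358 and 0.0451), and the median slope was 0.16, 0.11 and 0.05, against 0.14, 0.09 and 0.06 within slide 1 and 0.21, 0.19 and 0.03 within slide 2, for the 3 lists in the same order.

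High against low subclones asked which genes separate the ends of the TIMP1 range. DIO2, the deiodinase that activates thyroid hormone, was at least 24.9-fold higher in the high subclones (adjusted p = 0.0113), AK7, an adenylate kinase of motile cilia, at least 38.0-fold (adjusted p = 5.17e-05), KCNJ3, a G-protein-gated potassium channel, at least 15.3-fold (adjusted p = 0.00665), and CLSTN2, a synaptic calsyntenin, at least 8.08-fold (adjusted p = 0.0126). None of these 4 was well above background in a low or intermediate subclone. NRXN3, a neurexin (at least 8.0-fold, adjusted p = 0.0245), and FAM133A (at least 5.72-fold, adjusted p = 0.0412) were not well above background in the low subclones either, but were measured in 1 intermediate one. CSTA, a cystatin that inhibits cathepsins, was 32.5-fold higher (log2 5.02, SE 0.59, adjusted p = 0.00545) and CT45A5, a cancer/testis antigen, 18.0-fold (log2 4.17, SE 0.87, adjusted p = 0.0262).

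The other rises among the 12 largest were measured in 1 of the 2 low subclones. TMTC1 rose at least 33.5-fold, PRSS23, a secreted serine protease, at least 17.8-fold, TNFRSF10C, a decoy receptor for the death ligand TRAIL, at least 10.1-fold and TFPI, the inhibitor of the tissue factor pathway of coagulation, at least 15.97-fold, with adjusted p of 0.0177, 0.0207, 0.0205 and 0.00869. The size for TNFRSF10C rests much on subclone 2, below background, as low subclone 1 was at -3.10 against -1.44 to -0.32 in the high subclones. TIMP1 was 14.4-fold higher (log2 3.85, SE 0.32, adjusted p = 0.000875) and followed the 12.

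The 12 largest decreases included SULF1 and GPC6. SULF1, the sulphatase that removes sulphate from heparan sulphate at the cell surface, was at least 197-fold lower (adjusted p = 0.00517) and was well above background in 1 of the 6 high subclones. GPC6, a glypican that carries heparan sulphate, was at least 97.1-fold lower (adjusted p = 0.000179). PLS3, an actin bundler, was at least 83.8-fold lower (adjusted p = 0.0413), CALD1, the gene of caldesmon, at least 11.3-fold (adjusted p = 0.0217), and ADD3, an adducin, at least 19.96-fold (adjusted p = 0.0216). PLS3 and ADD3 were well above background in 1 and 2 of the high subclones. BTG3, an antiproliferative factor, was at least 40.4-fold lower (adjusted p = 0.0206), SLC4A10, a bicarbonate transporter, at least 12.9-fold (adjusted p = 0.00869), and PGR at least 28.2-fold. BRINP3 (at least 95.5-fold lower), CA2, a carbonic anhydrase (at least 85.1-fold), and ZNF462, a zinc finger protein (at least 62.9-fold), were measured in 2, 3 and 4 of the high subclones, with adjusted p of 0.015, 0.0262 and 0.0243. C9orf152, measured in all 10 subclones, fell by 4.97 (SE 0.67, adjusted p = 0.00901).

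In all, 947 probes were higher and 975 lower in high than in low subclones (limma, adjusted p under 0.05), naming 632 and 662 genes, and 400 and 450 of the probes differed by more than 2-fold. The genes named for size were those whose 6 high subclones all lay on one side of both low ones, which 7.14% of splits of 8 into 6 and 2 give by chance for a gene not chosen by size. The share of higher probes, 49.3%, was 60.8% after quantile normalisation and 68.8% after scaling to the median, so the balance of rises and falls depends on the scaling. The count was 1148, 1056, 773, 772, 756 and 1126 without subclone 1, 2, 5, 7, 9 and 10 respectively, and 14 of the 54 named genes that passed were called in each leave-one-out fit (AK7, BNIP3, C9orf152, CLSTN2, CSTA, DIO2, GPC6, KCNJ3, PGR, SLC4A10, SULF1, TFPI, TIMP1 and TNFRSF10C), the most losses, 36, coming without subclone 1. With the slide as a block 29 probes passed and 48 of the 54 named genes did not, although these 54 kept a median of 0.99 of their fitted difference (0.741 to 1.20). Slide 1 alone holds both classes, and 1 probe passed within it. All 54 genes had the sign of their fitted difference there, which the choice of these genes on the same arrays favours. For FN1, near the floor, that sign cannot be read as a direction. AK7, GPC6, SULF1, PGR and TIMP1 were among those still called with the block (adjusted p = 0.00511, 0.00574, 0.0331, 0.0239 and 0.0337; TIMP1 at 3.72). Within slide 1 the bounds of the leading 4 were 37.2-fold, 61.0-fold, 159-fold and 17.7-fold. The median of all probes moved from -0.06 to 0.07 with median scaling and to -0.21 without the filter on dim probes, where 509 probes passed. The count was 761, with 31 of the 54 named genes no longer called and a median of 0.998 of their fitted difference kept (0.596 to 1.30), with the negative-control signal of each array as a covariate, an alternative chosen after the data were seen.

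**Figure D3:**
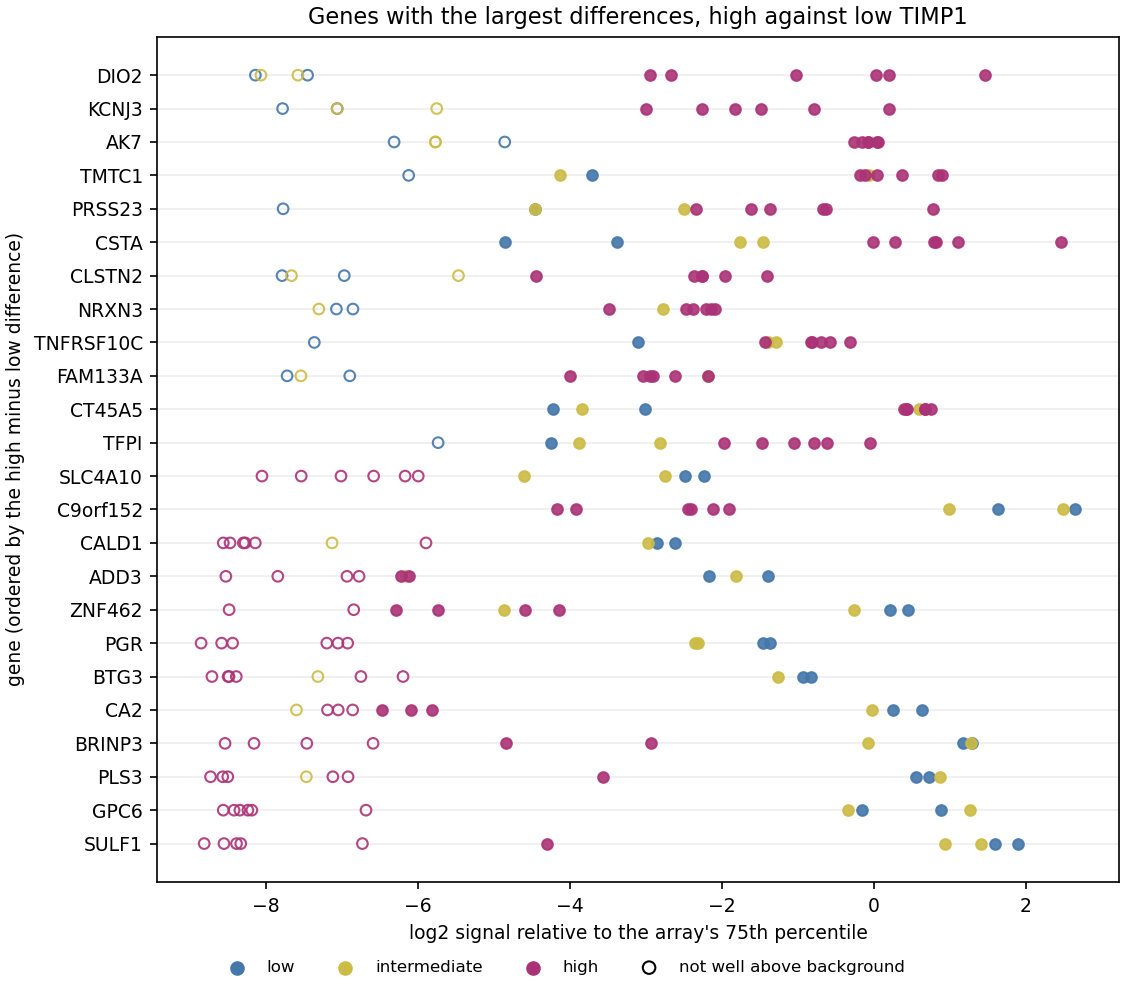
Log2 signal (horizontal axis, relative to the array's 75th percentile) of the 24 genes with the largest differences between high and low subclones, 1 point per subclone, coloured by class, with open points not well above background. PGR, GPC6, CALD1, BTG3 and SLC4A10 have 6 open points in the high class, and DIO2, KCNJ3, AK7 and CLSTN2 have open points in all 4 other subclones.

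Of all probes 8.02% were called in high against low, the share to set beside the counts of list members below. By gene list, oestrogen receptor target genes went both ways: 2 of 30 rose and 2 fell (3 and 3 adjusted over the list alone). CXCL12, a chemokine, rose by 1.26 (SE 0.28, adjusted p = 0.0299) and NRIP1, a corepressor of the receptor, by 0.70 (SE 0.15, adjusted p = 0.0295). TFF3, a secreted trefoil factor, fell by 1.71 (SE 0.41, adjusted p = 0.0387), and PGR fell. The other 3 CXCL12 probes did not pass and ran from -0.28 to 1.43. The list's median was 0.07 and its mean -0.17 (-0.12 with PGR at its bound), and camera gave an upward direction that did not pass (adjusted p = 0.815). Of 16 steroid receptors and cofactors, 3 coactivators or corepressors rose (NCOA3, 0.71; NRIP1, 0.70; NCOA1, 0.46) and PGR alone fell (3 and 2 adjusted over the list alone). The second NCOA1 probe was at -1.13 and the mean of both at -0.33, neither past the threshold, so the direction of NCOA1 depends on the probe. There too the median (0.02) and camera's direction were positive and the mean (-0.41, or -0.31 with PGR at its bound) negative (camera, adjusted p = 0.861). Of 20 luminal epithelial identity genes 1 rose, KRT8, a keratin of simple epithelia (0.97), and 1 fell, SPDEF, an ETS factor of luminal cells (-0.62), with 2 and 2 adjusted over the list alone.

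Matrix and surface genes went both ways. Of 20 metalloproteinases and inhibitors, 3 rose, TIMP1, TIMP4 (at least 3.31-fold, measured in 1 of the 2 low subclones) and MMP19 (0.84), and ADAM15, a membrane disintegrin, fell by 0.57 (3 and 2 adjusted over the list alone). Of 11 TIMP1 surface partners and integrins, ITGB5 rose by 1.0 and ITGAV by 0.62, the subunits of the vitronectin receptor (2 higher and 1 lower adjusted over the list alone). Of 14 mesenchymal and EMT genes, TWIST1, a transcription factor of mesenchymal cells, was at least 5.04-fold lower (2 and 2 adjusted over the list alone). FN1, fibronectin, also passed (adjusted p = 0.022), but it was measured in 4 high subclones alone, near the floor, so neither a fold nor a direction can be read. TWIST1 was measured in 3 of the high subclones. ERBB2, the HER2 receptor, fell by 0.54 and was the single member of 9 ERBB receptors and ligands to pass (2 higher and 1 lower adjusted over the list alone).

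Signalling and metabolic lists gave further members. Of 15 MAP kinase feedback genes, DUSP4 rose by 1.14 and SPRY2, a Sprouty inhibitor of receptor tyrosine kinase signalling, by 0.66 (5 and 0 adjusted over the list alone). Of 14 cell cycle inhibitors and p53 targets GADD45A rose by 1.33 (4 and 1 adjusted over the list alone), with low subclone 1 at -1.27 and low subclone 2 at -0.035. Of 25 cell cycle and proliferation genes RRM2, the regulated subunit of ribonucleotide reductase, rose by 0.93 (1 and 0 adjusted over the list alone). Of 15 cholesterol synthesis genes HMGCS1 rose by 1.07 and MSMO1 by 0.80 (4 and 0 adjusted over the list alone). Of 18 hypoxia and glycolysis genes, BNIP3, a mitophagy receptor induced by hypoxia, fell by 1.52, ANKRD37 fell by 1.38 and PFKFB3, a regulator of glycolysis, rose by 0.71 (1 and 3 adjusted over the list alone), the second PFKFB3 probe being at 0.07. Of 18 interferon-stimulated genes, MX2, an antiviral GTPase, fell by 1.31 and OAS3, an oligoadenylate synthetase, rose by 1.06, its second probe being at -0.00 (1 and 2 adjusted over the list alone). ABCC3, a drug efflux transporter, rose by 2.05, alone among 13 drug transporters and detoxification genes (1 and 0 adjusted over the list alone). Its size rests much on low subclone 1, at -2.20, as low subclone 2 was at 0.24. Of 6 topoisomerases TOP1 rose by 0.51, its second probe being at -0.11, and the mitochondrial TOP1MT fell by 0.70 (1 and 1 adjusted over the list alone). Adjusted p of the members named here and in the preceding paragraph, TIMP1 (0.000875) aside, ran from 0.00403 (BNIP3) to 0.0459 (PFKFB3 and SPRY2).

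No member passed over all probes in the other 11 lists, which were the basal markers, IGF and insulin signalling, anti-apoptotic genes (2 and 0 adjusted over the list alone), pro-apoptotic genes, NF-kB targets, the unfolded protein response, heat shock genes, the neighbours of TIMP1 on the X chromosome, fibroblast markers, blood and endothelial markers, and housekeeping genes. Of the 12 fibroblast and 12 blood and endothelial markers, 3 and 6 had a probe that passed the filter on dim probes. For IGF and insulin signalling the median (-0.21) and mean (-0.06) were negative and camera's direction positive (adjusted p = 0.861). Among all 26 lists, camera with its preset correlation called 1, cholesterol synthesis, as higher in high subclones (median 0.31, adjusted p = 0.0358; adjusted p = 0.891 with an estimated correlation), and the other 25 had an adjusted p of at least 0.0674. That call ended with the slide as a block (median 0.29, adjusted p = 0.103; the median within slide 1 was also 0.29), with median scaling (adjusted p = 0.0534), with probes well above background on all arrays (adjusted p = 0.054) and without subclone 1 (adjusted p = 0.254), 3 or 4 (adjusted p = 0.0578 each).

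**Figure D4:**
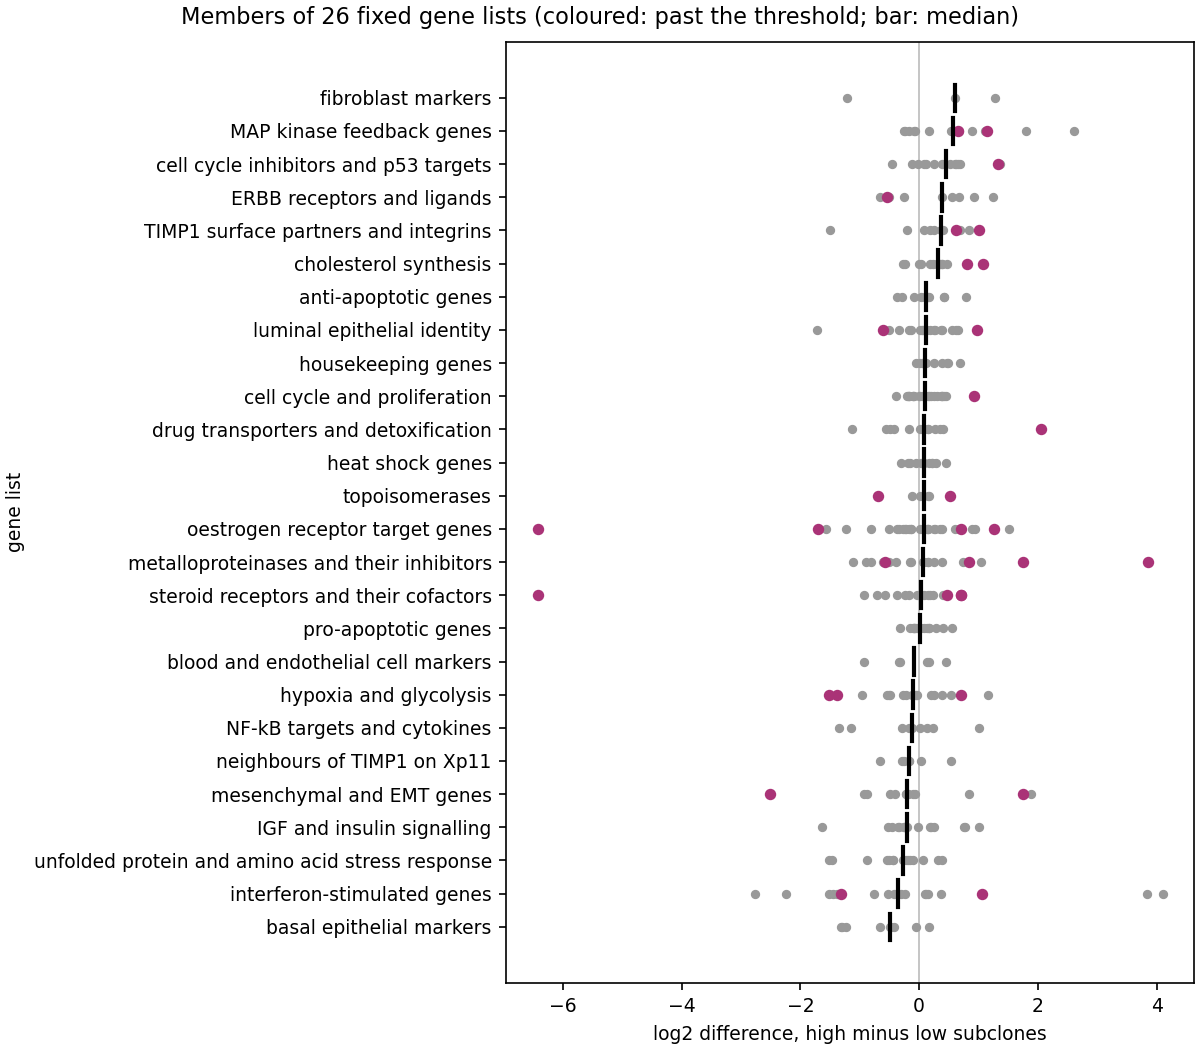
Log2 difference between high and low subclones (horizontal axis) of each tested member of the 26 gene lists, 1 point per gene, coloured where limma's adjusted p was under 0.05, with a bar at the list's median. PGR's fitted difference, which has only a bound, is drawn at -6.42 in both lists that hold it, and list medians lie between -0.50 and 0.60.

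Intermediate against low subclones gave no gene past the threshold (limma, 0 of 23977 probes; smallest adjusted p = 0.776), and 1354 probes had an unadjusted p under 0.05 where 1199 were expected by chance. TIMP1, the gene by which the classes were named, was 4.64-fold higher (log2 2.22, SE 0.39, adjusted p = 0.776). Of the 10 genes with the smallest p, ALCAM, a cell adhesion molecule, was at -2.57, RIN1, a RAS effector, at -3.18, PEX6, a peroxisome factor measured in 1 of the 2 intermediate subclones, at -2.13, RGL3 at -1.60 and SNX22 at -0.94, while LIMA1, an actin-binding protein, was at 1.26. ZNF284, C16orf92 and RGS20 were not well above background in the low subclones. In the intermediate ones ZNF284 was not either, and RGS20 was in 1. C16orf92 was in both, at least 1.59-fold higher. The adjusted p of these genes was 0.776 or 0.806. PGR was at -0.92 (SE 0.64, adjusted p = 0.864) and ESR1 at -0.08 (SE 0.23, adjusted p = 0.97). With 2 subclones on each side, 17.5% of simulated changes of 1 on the log2 scale and 77.5% of changes of 2 were recovered. The simulation drew noise independently for each probe and may recover more than the data allow. Fitted differences larger than 2, as for TIMP1, ALCAM and RIN1, did not pass here, so changes of that size could be missed too. The count was 1 after quantile normalisation, 310 without subclone 1, 5 without subclone 2, 7 without subclone 3, 57 without subclone 4, and 0 with the slide as a block, with array weights, with the authors' table and with only these 4 arrays in the fit.

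High against intermediate subclones asked the same of the upper part of the range, on the same 6 high arrays. DIO2 was at least 25.7-fold higher (adjusted p = 0.0141), AK7 at least 43.2-fold (adjusted p = 3.81e-05) and KCNJ3 at least 15.8-fold (adjusted p = 0.0141). They were joined by IFI44, an interferon-induced gene, at least 21.4-fold higher (adjusted p = 0.0435), and LEMD1, a cancer/testis antigen, at least 4.92-fold (adjusted p = 0.0364). GPC6 was at least 104-fold lower (adjusted p = 0.00016) and PGR at least 14.96-fold. SULF1, measured in 1 of the 6 high subclones, was at least 132-fold lower (adjusted p = 0.00579), BRINP3, measured in 2, at least 61.6-fold (adjusted p = 0.0261), and C9orf152 fell by 4.56 (SE 0.67, adjusted p = 0.0141). TIMP1 was 3.10-fold higher (log2 1.63, SE 0.32, adjusted p = 0.0289) and ESR1 was at -0.09 (SE 0.19, adjusted p = 0.799).

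By limma, 482 probes were higher and 747 lower in high than in intermediate subclones, naming 328 and 462 genes. The share of higher probes, 39.2%, was 56.4% after quantile normalisation, 50.8% after normexp background correction and 52.3% in the authors' table. The count was 2151 without subclone 1 or subclone 2, and 428, 155, 391, 432, 358 and 658 without subclone 3, 4, 5, 7, 9 and 10, and 4 of the 11 named genes that passed (AK7, GPC6, PGR and SULF1) were called in each leave-one-out fit. With the slide as a block 89 probes passed and 6 of the 11 named genes did not, among them TIMP1 (1.65, adjusted p = 0.112), although the 11 kept 0.90 to 1.05 of their fitted difference. Further, all 11 kept their direction within slide 2 and within slide 3, which holds 1 array of each class, as the choice of these genes on the same arrays favours. The count was 21 with the negative-control signal as a covariate, where 9 of the 11 named genes were no longer called, PGR (adjusted p = 0.13) and TIMP1 (0.58, adjusted p = 0.525) among them, and AK7 and GPC6 still were. The 11 kept a median of 0.871 of their fitted difference (0.356, for TIMP1, to 1.09). On slides 2 and 3 respectively, PGR was at least 19.0-fold and 17.9-fold lower, GPC6 at least 234-fold and 70.3-fold lower, AK7 at least 51.6-fold and 36.8-fold higher and DIO2 at least 38.4-fold and 6.11-fold higher. The slide 3 bound of PGR does not hold on its second probe. SULF1 was at least 258-fold lower on slide 2 and at -5.23 on slide 3, where both arrays measured it, and TIMP1 was at 1.53 and 1.82.

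High against low and intermediate subclones together gave the largest count of the comparisons between classes. AK7 was at least 40.5-fold higher (log2 signal -0.08 ± 0.12, SD, n = 6, in the high subclones; adjusted p = 1.08e-06), DIO2 at least 25.3-fold (adjusted p = 0.00124), KCNJ3 at least 15.6-fold (adjusted p = 0.00106) and CLSTN2 at least 8.21-fold (adjusted p = 0.00235). IFI44 was at least 13.1-fold higher (adjusted p = 0.0184), although it was well above background in low subclone 2, at -2.39. GPC6 was at least 101-fold lower (adjusted p = 3.39e-06) and PGR at least 20.5-fold (adjusted p = 8.66e-05). SULF1 was at least 161-fold lower (adjusted p = 0.000363) and BRINP3 at least 76.7-fold (adjusted p = 0.00247). PLS3 was lower too (adjusted p = 0.0362), with signals below the floor on both sides, and was no longer called with the slide as a block (adjusted p = 0.0688). TIMP1 rose by 2.74 (SE 0.50, adjusted p = 0.00785). ESR1 was at -0.13 on its brightest probe (SE 0.14, adjusted p = 0.538). On its other probes it was at -0.44 and -0.43 (adjusted p = 0.0792 and 0.0724). For 9 of the 12 genes named in this comparison, the values of the 6 high subclones did not overlap those of the other 4, which 0.952% of splits into 6 and 4 give by chance for a gene not chosen, as these were, by its difference. The exceptions were ESR1, IFI44 and PLS3.

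In this comparison limma called 1756 probes higher and 2583 lower, naming 1183 and 1658 genes, and 438 and 641 of the probes differed by more than 2-fold. The share of higher probes, 40.5%, was 56.5% after median scaling, 55.3% after quantile normalisation, 51.7% after normexp background correction and 52.9% in the authors' table. With the slide as a block 3149 probes passed, 2997 of them called in the same direction as before. Of the probes called over all arrays 100% had the same direction within slide 1, 100% within slide 2 and 93.8% within slide 3, shares that the choice of these probes on the same arrays favours. PLS3 was an exception on slide 3, where the high subclone alone was well above background. The count was 2046 without subclone 1, 1739 without subclone 4, and 2715, 2759 and 2786 without subclones 5, 7 and 9, and it was 832 with the negative-control signal as a covariate, where TIMP1 (adjusted p = 0.0826), IFI44 (adjusted p = 0.298) and PLS3 (adjusted p = 0.0936) were no longer called. The difference of TIMP1 was 2.75 with the covariate and 2.74 without it, the fitted one of IFI44 3.12 against 5.33, and that of PLS3 was not smaller.

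The differences between the high and the other subclones were not spread evenly along the genome. This description was chosen after the results were seen. When 14816 genes were put in chromosomal order and divided into 360 windows of 40 neighbours, 4 windows were more one-sided than any window in 1000 random orders, where the largest surplus of genes on one side of the median was 30. On the long arm of chromosome 1, from FLAD1 to SLC25A44, 39 of 40 genes were lower in the high subclones than the median difference of all genes (median of the window -0.52) and from OLFML2B to GORAB 37 of 40 were lower (median -0.42), while from APH1A to CELF3 37 of 40 were higher (median 0.40). On chromosome 9, from TRUB2 to PRDM12, 39 of 40 were higher (median 0.38). For single subclones, each gene was set relative to its mean over the low and intermediate subclones, so these 4 lie around 0 by construction. On that scale the median of the FLAD1 window lay between -0.66 and -0.27 in the high subclones, nearest 0 in subclone 8. It lay between -0.10 and 0.03 in the other 4. The window was itself picked for being one-sided in this comparison.

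**Figure D5:**
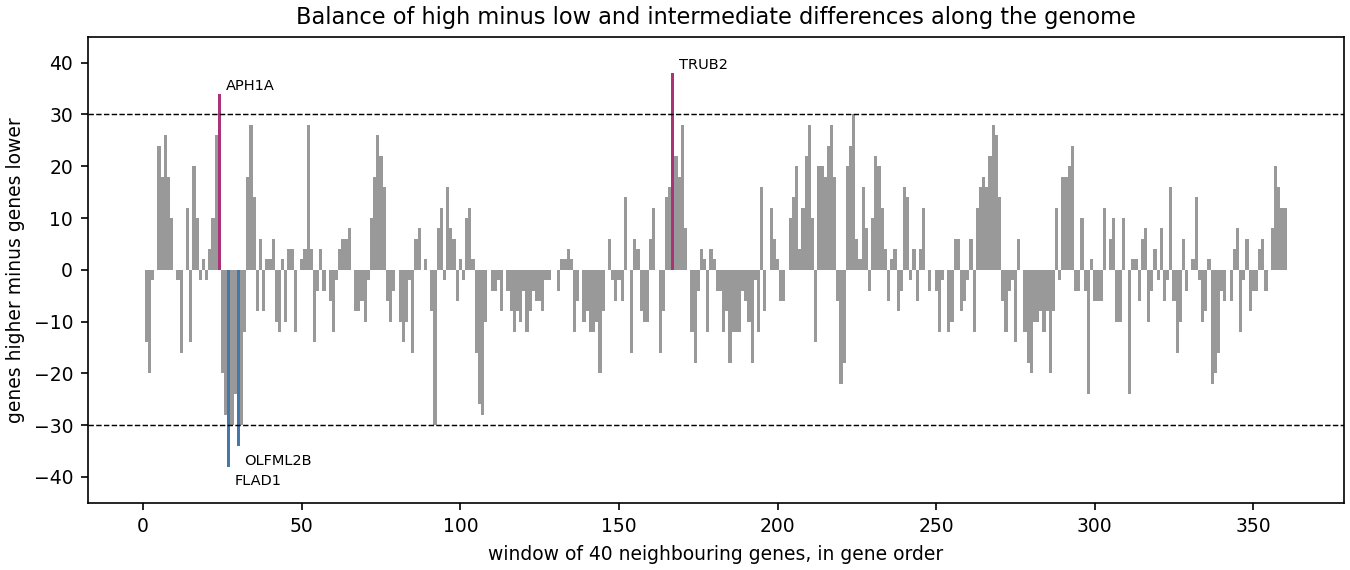
Number of genes higher minus number lower in the high subclones, relative to the median difference, in each of 360 consecutive windows of 40 neighbouring genes (horizontal axis, in chromosomal order; vertical axis, genes). Dashed lines mark the largest surplus in 1000 random orders, 30, and the 4 coloured windows, labelled by their leading gene, lie beyond it.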

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

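The checks for subclones far from their class were fixed in advance, and none of the values below was singled out by hand. Of 83 sets of 6 values from the high subclones, 12 held a subclone whose gap to the nearest other one was large against the range of the 6, where chance gives about 1 in 20, or 4.15; among 75 genes there were 7.

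The array of high subclone 6 stood apart 7 times. Its negative-control signal was 63.9 (30.8 to 34.9 on the other high arrays), its 75th percentile 1216 (997 to 1039), its share of probes well above background 55.2% (64.9% to 68.2%), its number of outlier spots 531 (201 to 237) and its score on component 3 -61.3 (-2.78 to 17.5). CALD1, an actin-binding regulator of contraction, was at -5.89 there (-8.56 to -8.14 in the others) and GPC6, a glypican, at -6.68 (-8.56 to -8.18), and neither was well above background on any of the 6.

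In high subclone 8, CLSTN2, a calsyntenin, was lower (-4.45 against -2.37 to -1.40) and PLS3, an actin bundler, was higher (-3.56 against -8.73 to -6.92) than in the other high subclones, where PLS3 was not well above background. COL24A1, a collagen, was at -6.25 in subclone 9 (-5.79 to -5.59 in the others), where it was not well above background, as in subclones 5 and 6, so no difference can be read. GPR158, an orphan receptor, was at -8.25 in subclone 7 (-7.10 to -6.42 in the others), but no high subclone was well above background, so no difference can be read there either. NRXN3, a neurexin, was lower in subclone 10 (-3.48 against -2.48 to -2.09).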

How the results depend on the processing

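The fits within a slide, with the background covariate and without subclones 2 and 6 were chosen after the data were seen. Of the 83 calls of named genes, 1 reversed under the alternatives run for them: NCOA1 in high against low was at -0.33 with the mean of a gene's probes. In 1421 of 2048 gene and setting pairs the call was kept and in 626 it was lost, and of 496 pairs of uncalled genes 34 gained one. The correlation of ESR1 with protein was run with the other scalings, the mean of its probes, the authors' table, unlogged or ranked protein and single omissions, and passed in none of these.

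Probes trending with TIMP1 protein (10) were 4 with quantile normalisation, 16 with median scaling, 5 without the filter on dim probes, 32 with probes well above background on all arrays, 56 with trend and robust, 10793 with array weights (weight 5.13 for subclone 1), 24 in the authors' table, 0 with the slide as a fixed block and 71 as a random one, 1 with unlogged protein, 21 with ranks, 1634 with TIMP1 mRNA, 0 without subclones 2 and 6, 0 in slide 1, 0 in slide 2 and 0 with the background covariate.

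For high against low (1922) the count was 509 without the filter, 37 with array weights, 29 with the fixed and 3385 with the random block, 1 in slide 1 and 761 with the background covariate. For intermediate against low (0) it was 1 with quantile normalisation and 7 without subclones 2 and 6. For high against intermediate (1229) it was 248 without the filter, 89 with the fixed block, 2151 with only these classes, 2889 without subclones 2 and 6, 321 in slide 2 and 21 with the background covariate. For high against the rest (4339) it was 10284 with array weights (weight 3.49 for subclone 4), 1 in slide 1, 321 in slide 2 and 832 with the background covariate; the other alternatives, single omissions aside, stayed within 1.5 times.

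Lists past the threshold numbered 3 in the trend, 6 without the filter and 0 with an estimated correlation. In high against low there was 1, and 3 with normexp, 0 with median scaling, 6 without the filter, 0 with probes well above background on all arrays, 4 with trend and robust, 3 with array weights, 2 in the authors' table, 0 with the fixed block, 3 with the mean of a gene's probes and 0 with an estimated correlation. The correlation of TIMP1 mRNA with unlogged protein, 0.67, no longer passed.

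Leaving out 1 subclone gave 0 to 1441 probes in the trend, 756 to 2335 in high against low, 0 to 310 in intermediate against low, 155 to 2151 in high against intermediate, 1739 to 5406 in high against the rest, 2 to 4 lists in the trend, 0 to 3 lists in high against low, and correlations with protein of 0.925 to 0.977 for TIMP1 and -0.308 to 0.0566 for ESR1; a lone subclone left in a class was assumed to vary like the others. The 2 lists that passed in the trend without subclone 1 were not among the 3 called over all arrays. Fewer arrays account for part of the loss within slides, and the filter sets how many probes are tested. Otherwise the cause was not tested. Lists gave no value with the random block, and a fit of the array weights stopped short of convergence, so counts with weights are uncertain. No paired analysis was possible because the classes share no replicate numbers. Signal over background limits low genes: folds against signals below the floor are bounds, while fitted values, p-values, slopes and list averages still use those signals.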

Other observations

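The lists in high against low and intermediate subclones together, the account of subclone 3, and the tests of slide, array background, gene order and PGR were chosen after results were seen; those of other splits, dim signal and a graded response were set before.

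In high against low and intermediate subclones together, 18.1% of all probes were called, the share to set beside the counts of list members below. Interferon-stimulated genes parted. IFI44 and IFI44L, neighbouring antiviral genes, were higher, each well above background in all 6 high and in 1 of the 4 other subclones (IFI44 at least 13.1-fold), and OAS3 (0.88 on one probe, -0.04 on the other) and IRF9 (0.44) were higher too. BST2, which tethers budding viruses to the cell (-2.80), MX2 (-1.02) and IRF7, a regulator of the interferon response (-0.86), were lower (limma, 4 of 18 higher and 3 lower; 4 and 4 adjusted over the list alone). The list's median was -0.27 and its mean 0.04, and camera did not call it (adjusted p = 0.855). Of 20 luminal identity genes, MUC1, an apical mucin (-1.66), AGR2, a disulphide isomerase (-0.74), and SPDEF (-0.59) fell while KRT8 (0.85) and ANXA9 (0.79) rose (5 and 4 adjusted over the list alone). The second MUC1 probe was at -0.55 and did not pass. The androgen receptor AR fell by 0.62 and the glucocorticoid receptor NR3C1 fell by 0.90, the latter on both probes, besides PGR (1 of 16 steroid receptors and cofactors higher, 3 lower; 3 and 5 adjusted over the list alone).

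MAP kinase feedback genes were higher in high subclones with 5 of 15 past the threshold and 0 lower (5 and 0 adjusted over the list alone): PHLDA1 (2.83 as fitted, well above background in 1 of the 4 other subclones), ETV5 (1.77, in 2 of the 4), DUSP5 (1.05), ETV4 (0.73) and SPRY2 (0.53). Of 14 cell cycle inhibitors and p53 targets BTG2 (1.65), GADD45A (1.11) and PLK3 (0.61) rose and RRM2B (-0.41; second probe -0.03) fell (5 and 1 adjusted over the list alone). Camera called both lists (adjusted p = 0.0428 each; adjusted p = 0.801 with an estimated correlation). Of 10 anti-apoptotic genes MCL1 (0.81) and BCL2L2 (0.50), which restrain apoptosis, rose and 0 fell (2 and 0 adjusted over the list alone). That share is near the 18.1% of all probes called in this comparison.

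Intermediate subclone 3 lay near the high subclones for some of the genes that separate high from low. Its array had the highest negative-control signal, 100.2, against 68.6 for intermediate subclone 4. CALD1, BTG3, CA2 and PLS3 were not well above background there and were at -2.97, -1.26, -0.02 and 0.88 in intermediate subclone 4. NRXN3 was at -2.77 in subclone 3 and not well above background in subclone 4, CT45A5 at 0.59 and -3.84, and TMTC1 at -0.06 and -4.13. PGR (-2.31 and -2.36) and AK7, GPC6 and DIO2, which separated all 6 high subclones from the other 4, did not show this.

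High subclones stood apart from low and intermediate ones by 4339 probes. Of 100 sampled splits into 6 and 4, 1, the real one, gave as many, and the highest other gave 102. That argues against a random split of independent subclones. The labels do not say that the subclones are independent. The splits therefore cannot exclude that the high subclones are related and share the TIMP1 class by chance. A slide difference as the whole cause is argued against by 69.07% of the 4339 probes still being called with the slide as a block, and signal near background by a share called among probes above background on all arrays of 0.968 times that among all. Array background as the whole cause is argued against by the fit with it as a covariate, where the differences of these probes kept a median of 0.924 of their size (quartiles 0.681 and 1.16) and 832 probes were called, 595 of them among the 4339, against at most 78 in 99 other splits (medians went from 0.67 to 0.60 for the difference and from 0.154 to 0.22 for its standard error, so calls ended more by wider errors than by smaller differences). A part for background stays open, as subclone 6, the high array with a background like the low ones, lay at a median place of 0.668 between the low and intermediate mean and the mean of the other high subclones, and so does a graded response to TIMP1, with slopes within the high subclones at a median of 0.316 of those over all 10 (0.194 to 0.588 leaving out 1 high subclone) and those within the low and intermediate ones at 0.0943 (-0.303 to 0.347 leaving out 1). A candidate explanation is that the high subclones share genome segments of altered copy number, since differences of genes 20 places apart correlated at 0.0929 (across genes, which are not independent; at most 0.0266 in 1000 random orders), but differences between subclones of 1 class correlated too (up to 0.107 among low and intermediate, median 0.05, and up to 0.0924 among high, median 0.0415, against a median of 0.079 between them), so the value is not particular to the classes; copy number was not measured here, and regional or GC-linked bias could give the same.

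On the probe used here PGR lay below background in each of the 6 high subclones, while a second probe measured it in high subclone 8. A common fall of oestrogen receptor target genes is argued against by the other 29, whose mean difference between high and the rest was 0.108, with 3 higher and 2 lower. Its SE of 0.131 was taken over genes and is too small, as they are not independent (estimated correlation of the list 0.144). A mean over genes that go both ways does not measure receptor output, so a partial loss stays open. A fall of ESR1 mRNA by 1 or more on the log2 scale is argued against by all 3 probes. The difference was -0.129 on the brightest (95% interval -0.44 to 0.18). It was -0.44 and -0.43 on the other 2 (95% intervals -0.79 to -0.08 and -0.77 to -0.09; limma, adjusted p = 0.0792 and 0.0724). The intervals of these 2 probes lie below 0, although neither passed the threshold, so a smaller decrease stays open. A higher detection floor of the high arrays is argued against on the probe used here. The lowest PGR signal of the low and intermediate arrays lay 2.38 above the highest detection floor of the high ones. A part for array background stays open. With the negative-control signal as a covariate, the PGR call against the rest held (limma, adjusted p = 0.01), and that against intermediate did not (adjusted p = 0.13). A change at the PGR gene itself or in its other regulators may remain, and neither receptor protein nor its activity was analysed here.

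For the 10 probes that trended with TIMP1 protein, 4 of 100 sampled assignments of the protein levels gave as many, the real one included. That is below the 0.05 set in advance, but by too little for 100 assignments to exclude chance. TIMP1, whose protein level is the covariate, is itself among the 10. The highest other assignment gave 405. Components 1 and 2 held 80.6% of the variance of that assignment, 66.4% of that of the real one and a median of 14.3% of the others, and no cause was tested. The trend may largely restate the step between high and other subclones: of as many probes with the smallest trend p as were called in high against the rest, 67.9% were fitted better by the step, and the TIMP1 slope was 0.17 within the high subclones against 0.69 over all 10. No probe passed with the slide as a fixed block (0), although the slopes of the 7 named genes kept 0.983 or more of their size, so the loss does not speak for the slide as their cause.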
